A study of Homo sapiens with 14 samples.

How the data were processed

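The analysis used the authors' deposited RSEM gene tables, which per the file headers hold expected counts for 78686 gene identifiers in each of 14 libraries. The submitters name STAR 2.7.10b, RSEM without a version, DESeq2 1.48.1 and the hg38 (GRCh38) genome, without saying what each was used for. Expected counts were rounded to whole numbers before testing. The annotation release is not stated. Symbols were found for 61463 identifiers (78.1%), and positions and biotypes from GENCODE 29 for 57288 (72.8%), which left some genes without a position. No reads were aligned here, so mapping, strandedness and contamination could not be re-examined.

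Each set was fitted on its own with edgeR 4.0.16 in R 4.3.3, using TMM factors, quasi-likelihood F tests and 1 coefficient per group. The 3 h libraries of both sets were fitted with 1 coefficient per group to test the difference between sets. They were also fitted with a term for set and 1 treatment coefficient, to estimate the effect common to both sets. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19049 genes in the time-course set, 17251 in the Nutlin set and 18873 in the fit of 3 h libraries from both sets. The biological coefficient of variation was 0.176, 0.114 and 0.12 in these fits, with 3, 4 and 4 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg across the tested genes, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of its F statistic. Levels are CPM after TMM within a set and are not comparable between sets, and log CPM used a prior count of 2.

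The comparisons were 3 h and 12 h of 5-Ph-IAA with vehicle and with each other, Nutlin with vehicle in each arm, and 5-Ph-IAA with vehicle with and without Nutlin. Further comparisons were the interaction of 5-Ph-IAA and Nutlin, the Nutlin effect averaged over both arms, the 3 h effect common to both sets, and its difference between sets. The difference between responses with and without 5-Ph-IAA was tested by an exact two-sided permutation of the 5-Ph-IAA labels. These were exchanged among the Nutlin libraries and among the libraries without Nutlin, with 36 assignments and a smallest p of 0.0556. Overlaps were tested with a one-sided Fisher test on the genes tested. With 2 libraries per group, a rank or permutation test of a single gene could not pass the threshold, so genes were tested with edgeR, which shares information between genes.

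The 27 gene lists were p53 targets and their growth-arrest, cell-death, and repair and metabolism parts, G2 and mitosis, S phase, replication histones, nuclear speckles and splicing, the hnRNP family, nuclear architecture, nuclear noncoding RNAs and snoRNA hosts, immediate early genes, the integrated stress and unfolded protein response, heat shock, interferon, NF-kB and inflammation, AHR and xenobiotic response, cholesterol and SREBP, hypoxia and glycolysis, Wnt targets, ribosomal proteins, ribosome biogenesis, mitochondrially encoded genes, colon epithelium, EMT and TGF-beta, other cell types, and long neuronal genes. They came from general knowledge and not from these libraries. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 27 lists. A count over the list alone adjusts the edgeR p-values over its members only. Values across genes of a list are not independent replicates.

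Genes were named by a fixed rule. HNRNPU, MDM2 and CDKN1A are named everywhere. Next come up to 10 genes raised and 10 lowered with the greatest change among those that passed, had a mean log2 CPM of at least 1, a symbol, and groups whose libraries did not overlap. From each list come up to 4 members that passed, by p, or the 2 most expressed where none passed. Some genes that the rule picks, and 1 of the 12 genes that differed between the sets at 3 h, are not reported here. Levels are given only for some of the others.

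Alternatives planned in advance were the Wald test of DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, each library left out in turn, the compared groups only, all 14 libraries in 1 fit, and protein-coding genes only (19827 in GENCODE 29). Chosen after seeing the data were a GC correction, genes with whole expected counts in every library (66501), libraries of the time-course set thinned to the shallowest, and the p53 list without its stress members. The GC correction subtracts a lowess trend (span 0.3) of log2 expression on the GC percent of the longest transcript, known for 89.6% of tested genes, from each library. Replicate numbers were treated as labels, since deviations of libraries with the same number correlated from -0.321 to 0.156 across genes.

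The tests were checked on simulated data with 200 changed genes, at the depth of the libraries and the spread of each gene in the fit. That spread was the same for every group. Real replicate pairs had a biological coefficient of variation from 0.053 (5-Ph-IAA, Nutlin set) to 0.229 (vehicle, time-course set). The recovered shares, false calls and slopes below therefore hold only for groups of equal spread. At 2-fold, edgeR recovered 45.5% for 3 h with vehicle, 54.8% for 12 h with vehicle, 49.3% for Nutlin with vehicle, 54% for 5-Ph-IAA with vehicle in the Nutlin set, 35.4% for the interaction and 43.9% for the difference between sets. At 1.5-fold the interaction recovered 3.08% and 5-Ph-IAA with vehicle 20.6%. False calls made up 11.9% for 3 h, 13.8% for 12 h, 9.65% for Nutlin, 4.72% for 5-Ph-IAA in the Nutlin set, 8.33% for the interaction and 6.82% for the difference between sets, above the nominal level in all but the 5-Ph-IAA comparison of the Nutlin set. A simulated response slope of 1 was estimated at 0.994 and a slope of 0.8 at 0.781. With a GC trend added to simulated counts, edgeR found 106 of 189 changed genes with 2911 false calls, against 92 with 8 false calls after the correction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.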

Results

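RNA was sequenced from HCT116 colon carcinoma cells that carry osTIR1(F74G) and a SAF-A protein (gene HNRNPU) fused to mAID and Halo tags. In such cells the auxin analog 5-Ph-IAA directs degradation of SAF-A, an RNA-binding protein of the nuclear matrix. The 14 stranded, rRNA-depleted total RNA libraries formed 7 groups of n = 2, which the titles place in what was read as 2 sets. The time-course set held vehicle (DMSO), 3 h of 5-Ph-IAA and 12 h of 5-Ph-IAA. The Nutlin set held vehicle, Nutlin (an MDM2 inhibitor that activates p53), 5-Ph-IAA, and 5-Ph-IAA with Nutlin. Its treated libraries are labelled 3 h, without saying which drug the time belongs to, and no Nutlin dose is given.

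Libraries of the time-course set held 33.7 and 34.1 M expected counts for vehicle, where M stands for 1e6 counts, 35.1 and 33.5 M at 3 h, and 29.6 and 3.54 M at 12 h. In the Nutlin set the totals were 15.6 and 13.2 M for vehicle, 12.6 and 17.2 M for Nutlin, 16.4 and 13.03 M for 5-Ph-IAA, and 15.3 and 16.2 M for the combination. After the low-count filter, 19049 genes were tested in the time-course set and 17251 in the Nutlin set. The labels do not say whether replicates were separate cultures, and if they were not, the p-values measure only the spread between these samples. Replicates varied by more than counting error, with a chi-square per degree of freedom from 3.28 between 5-Ph-IAA replicates of the Nutlin set to 22.2 between Nutlin replicates. A value of 1 would mean counting error alone, which covers neither PCR copies, since no molecular tags are described, nor variation between cultures. Levels below are normalised counts per M (CPM) within a set, as mean ± SD with n = 2, and log2 fold changes carry ± SE.

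Among genes picked by the naming rule, Nutlin most strongly raised those of the integrated stress response. This is the program that ATF4 and DDIT3 run under amino acid or protein-folding stress. CHAC1, an enzyme that breaks down glutathione, rose from 3.24 ± 0.126 to 66.4 ± 8.42 CPM, DDIT3, the stress transcription factor CHOP, from 14.8 ± 0.515 to 150 ± 3.56 CPM, and DDIT4, an inhibitor of mTORC1, from 56.5 ± 10.4 to 556 ± 44.6 CPM. Genes listed here as p53 targets rose less. CDKN1A, which encodes the cell cycle inhibitor p21, went from 199 ± 1.97 to 528 ± 12.7 CPM, a fold of 2.66. Raised with them were BBC3 and PMAIP1, which promote apoptosis, and GADD45A and BTG2, which restrain growth. AXIN2, a feedback inhibitor and target of Wnt signaling, fell from 8.01 ± 0.442 to 2.18 ± 0.233 CPM.

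The question in this comparison was what Nutlin changed in cells not given 5-Ph-IAA. By edgeR, 80 of 17251 genes passed an adjusted p of 0.05, 68 up and 12 down, and 39 of them moved at least 2-fold. CHAC1 (ENSG00000128965.13, chromosome 15, 40952962 to 40956519, + strand) had a log2 fold change of 4.35 ± 0.17 (adjusted p = 1.34e-06). DDIT3 (ENSG00000175197.13, chromosome 12, 57516588 to 57521737, - strand) had 3.34 ± 0.12 and DDIT4 (ENSG00000168209.6, chromosome 10, 72273920 to 72276036, + strand) had 3.30 ± 0.14. Next by size came SLC7A11-AS1 at 2.87, TSC22D3, a glucocorticoid-induced leucine zipper gene, at 2.71 ± 0.16, and LURAP1L at 2.65. GDF15, a secreted factor that p53 and cell stress both induce (ENSG00000130513.7, chromosome 19, 18374731 to 18389176, + strand), rose from 40.0 ± 4.55 to 214 ± 32.2 CPM, or 2.42 ± 0.13 (adjusted p = 1.18e-05). ATF3, a stress-induced transcription factor, rose by 2.21 ± 0.12, SESN2, a sensor of leucine that restrains mTORC1, by 2.17 ± 0.12, and SLC7A11, the cystine transporter, by 2.08 ± 0.10. CDKN1A (ENSG00000124762.15, chromosome 6, 36676460 to 36687339, + strand) rose by 1.41 ± 0.087 (adjusted p = 3.16e-05).

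**Figure D1:**
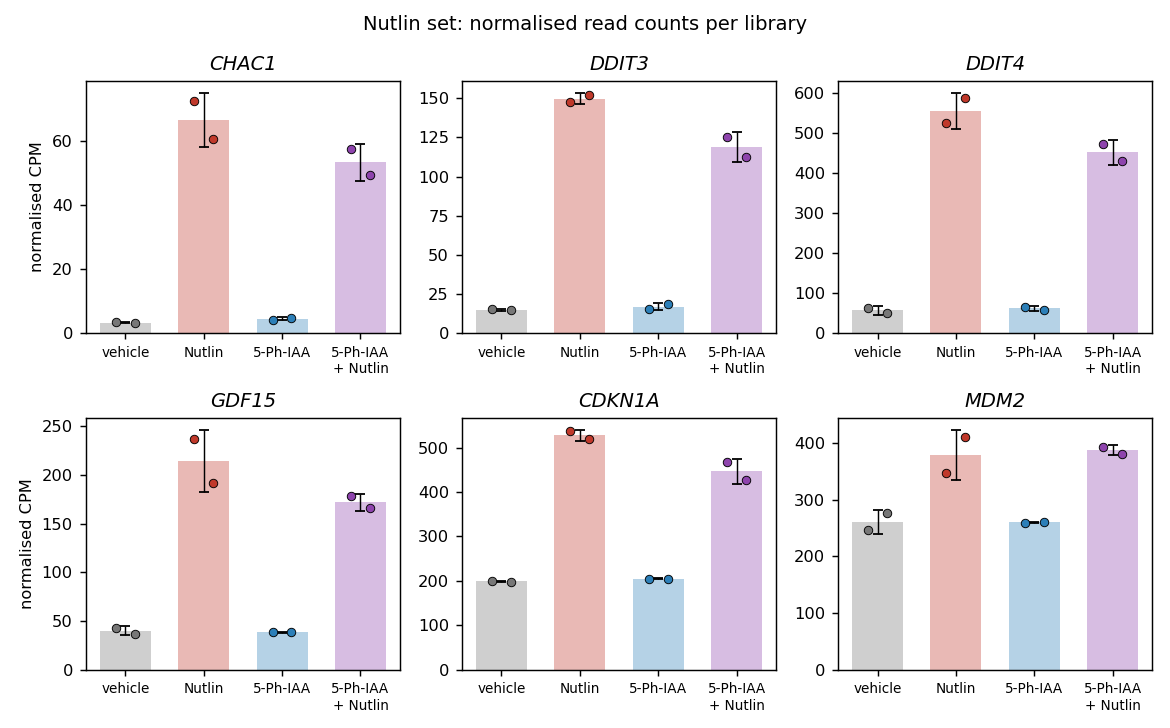
Normalised CPM (bars, mean; error bars, SD, n = 2; points, libraries) of CHAC1, DDIT3, DDIT4, GDF15, CDKN1A and MDM2 in vehicle, Nutlin, 5-Ph-IAA, and 5-Ph-IAA with Nutlin. CHAC1 went from 3.24 to 66.4 CPM with Nutlin alone and from 4.46 to 53.2 CPM in 5-Ph-IAA cells.

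Among lists fixed in advance, 17 of 27 measured stress-response genes rose and 0 fell, or 21 and 0 when adjusted over the list alone, with a median log2 fold change of 0.96 (edgeR counts; camera adjusted p = 7.81e-188, and adjusted p = 0.0004 with an estimated correlation). Of 88 p53 targets, 11 rose and 0 fell, or 29 and 2 over the list alone, with a median of 0.18 (adjusted p = 1.17e-22, and adjusted p = 0.00221 with an estimated correlation). ATF3, GDF15 and SESN2 are among these 11, and cell stress is known to induce all 3 of them, though only SESN2 is also on the stress list. Without SESN2, 10 of 87 p53 targets rose. The lists cannot separate a p53 response from a stress response, since membership does not show what raised a gene. Growth-arrest targets of p53 rose in 4 of 11 cases, or 6 over the list alone, with GADD45A at 1.14 ± 0.12 (adjusted p = 0.00196), PLK3, a stress-activated kinase, at 1.22 ± 0.17 (adjusted p = 0.0136) and BTG2 at 0.87 (adjusted p = 0.027). Camera gave that list an adjusted p of 6.64e-15, and adjusted p = 0.00742 with an estimated correlation. Cell-death targets rose in 3 of 15 cases, or 6 up and 1 down over the list alone, with BBC3 at 1.13 ± 0.17 (adjusted p = 0.0204), PMAIP1 at 0.70 (adjusted p = 0.0398) and TNFRSF10B, a TRAIL receptor, at 0.54 (adjusted p = 0.0398). For that list the adjusted p was 1.05e-05, and adjusted p = 0.0623 with an estimated correlation. Of 12 repair and metabolism targets, SESN2 alone rose, or 6 over the list alone (adjusted p = 6.13e-10, and adjusted p = 0.0461 with an estimated correlation).

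MDM2, the ubiquitin ligase of p53 and itself a p53 target (ENSG00000135679.27, chromosome 12, 68808176 to 68850686, + strand), stood at 261 ± 20.9 CPM in vehicle and 379 ± 44.5 CPM with Nutlin, a log2 fold change of 0.54 ± 0.10 (adjusted p = 0.0661). It passed without Nutlin replicate 1, at 0.66, and without Nutlin replicate 2, at 0.41. HNRNPU (ENSG00000153187.21, chromosome 1, 244840638 to 244864560, - strand) had -0.24 (adjusted p = 0.405) and passed without Nutlin replicate 2, at -0.34.

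Genes of cholesterol synthesis and uptake rose in 3 of 27 cases, or 13 over the list alone, with a camera adjusted p of 1.23e-17, and adjusted p = 0.00536 with an estimated correlation. Among them were INSIG1, which holds SREBP in the endoplasmic reticulum, at 0.82 (adjusted p = 0.0204), and MVK, mevalonate kinase, at 0.61, which no longer passed after GC correction (adjusted p = 0.0648). Wnt targets fell in 2 of 15 cases, or 3 over the list alone. These were AXIN2 (ENSG00000168646.14, chromosome 17, 65528563 to 65561647, - strand) at -1.88 ± 0.24 (adjusted p = 0.00745) and BMP4, a secreted growth factor, at -0.84 (adjusted p = 0.00829). The Wnt list had adjusted p = 1.7e-05, adjusted p = 0.165 with an estimated correlation, and adjusted p = 0.0625 without Nutlin replicate 2. Immediate early genes split 3 up and 1 down of 28, or 3 and 3 over the list alone, with JUN at 0.86 ± 0.094 and FOSB at -0.89. Their camera adjusted p was 0.0114, and adjusted p = 0.431 with an estimated correlation. It was 0.062 without vehicle replicate 2, 0.563 without Nutlin replicate 1, and 0.0766 after GC correction. Also lowered was CDC25A, the phosphatase that drives S phase entry, at -0.57 (adjusted p = 0.0481), and raised were VEGFA, the angiogenic growth factor, at 1.12 and HERPUD1, an endoplasmic reticulum stress gene, at 1.89 ± 0.088.

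The Nutlin replicates stood apart from each other and from the other libraries of their set, replicate 2 at -58.3 on the first principal component, which held 22.5% of the variance, and replicate 1 at -42.2 on the second, with 20.6%. The mitochondrial share was 0.189% of counts in replicate 2 against 0.311% in replicate 1. The other libraries of the Nutlin set held 0.289% to 0.344%, and the vehicle and 3 h libraries of the time-course set 0.163% to 0.215%. Across genes, the difference between the Nutlin replicates correlated at 0.435 with that between the vehicle groups of the sets, a comparison chosen after the results were seen. Its cause was not tested. Histone genes of DNA replication moved with the Nutlin pair. Of 34 members 1, H2BC13 at 0.62 ± 0.099, rose, 24 rose over the list alone, and the list median was 0.39 (adjusted p = 1.17e-22, and adjusted p = 0.165 with an estimated correlation). The histone median was 0.51, with 29 of 35 raised, without Nutlin replicate 1, and 0.24, with 9 of 34 raised, without replicate 2. Mitochondrially encoded genes passed in 0 of 15 cases and had a median of -0.43 (adjusted p = 3.51e-05, and adjusted p = 0.38 with an estimated correlation). Their median was -0.52, with 8 lowered, without Nutlin replicate 1, -0.22 (adjusted p = 0.16) without Nutlin replicate 2, and -0.063 (adjusted p = 0.297) without vehicle replicate 1. Ribosomal protein genes passed in 0 of 74 cases (adjusted p = 5.76e-07, and adjusted p = 0.616 with an estimated correlation), against 45 raised without Nutlin replicate 1 and an adjusted p of 0.506 for the list without replicate 2. The count of called genes was 25 and 26 without vehicle replicate 1 and 2, and 2131 (838 up, 1293 down) and 1177 (414 up, 763 down) without Nutlin replicate 1 and 2, where most called genes were lowered. In a fit of the compared groups only it was 27. Both fits without a Nutlin library kept all 80 genes, and in each reduced fit the lone library is assumed to vary like the other groups. Without vehicle replicate 1 and 2, respectively, calls were lost for BBC3 (1.31 and 0.99), GADD45A (1.12 and 1.16), BTG2 (1.06 and 0.71), PLK3 (1.07 and 1.39), PMAIP1 (0.62 and 0.80), TNFRSF10B (0.55 and 0.54), INSIG1 (0.79 and 0.85), MVK (0.62 and 0.61), AXIN2 (-1.94 and -1.82), BMP4 (-0.78 and -0.88), JUN (0.89 and 0.83), FOSB (-0.82 and -0.95), CDC25A (-0.52 and -0.61) and H2BC13 (0.66 and 0.59). SLC7A11-AS1 lost its call without vehicle replicate 2, at 2.46.

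In cells given 5-Ph-IAA, Nutlin again raised stress genes, and CHAC1 rose most among genes picked by the naming rule. CHAC1 rose from 4.46 ± 0.487 to 53.2 ± 5.72 CPM, DDIT3 from 16.8 ± 2.12 to 119 ± 9.42 CPM, and DDIT4 from 61.8 ± 6.21 to 452 ± 30.3 CPM. GDF15 rose from 38.6 ± 0.512 to 172 ± 8.88 CPM and CDKN1A from 205 ± 0.335 to 447 ± 28.6 CPM, a fold of 2.18. The apoptosis genes BBC3 and PMAIP1 rose here too, and AXIN2 fell from 8.23 ± 0.966 to 2.93 ± 0.647 CPM.

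This comparison asked what Nutlin changed in cells that were given 5-Ph-IAA. By edgeR, 67 of 17251 genes passed, 59 up and 8 down, and 622, 333 up and 289 down, in a fit of the compared groups only. CHAC1 had a log2 fold change of 3.58 ± 0.16 (adjusted p = 5.71e-06), DDIT4 2.87 ± 0.14, DDIT3 2.83 ± 0.12, GDF15 2.15, ATF3 2.14, SESN2 2.07, SLC7A11 1.95, HERPUD1 1.84 and CDKN1A 1.12 ± 0.087 (adjusted p = 0.000215). ADM2, a secreted peptide gene, rose by 3.08 ± 0.52 (adjusted p = 0.0424), SLC7A11-AS1 by 3.30, TSC22D3 by 2.50 and LURAP1L by 2.30. BTG2 rose by 1.12 (adjusted p = 0.00677), BBC3 by 1.10 (adjusted p = 0.028), PLK3 by 0.996, GADD45A by 0.98, JUN by 0.77 and PMAIP1 by 0.71. AXIN2 fell by 1.482 ± 0.23 (adjusted p = 0.0269), CDC25A by 0.65, MSX1, a homeobox transcription factor, by 0.83, and TNFRSF10D, a decoy receptor for TRAIL and the 1 lowered member of the p53 list, by 0.76 (adjusted p = 0.00633). MDM2 had 0.57 (adjusted p = 0.0617) and HNRNPU -0.11 (adjusted p = 0.875).

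Of 27 stress-response genes, 16 rose and 0 fell, or 21 and 0 over the list alone, with a median of 0.85 (camera adjusted p = 3.27e-181, and adjusted p = 0.000589 with an estimated correlation). The p53 targets split 9 up and 1 down of 88, or 17 and 1 over the list alone, with a median of 0.13 (adjusted p = 1.37e-17, and adjusted p = 0.00364 with an estimated correlation). Growth-arrest targets rose in 4 of 11 cases, or 5 over the list alone (adjusted p = 5.8e-12, and adjusted p = 0.0114 with an estimated correlation). Cell-death targets split 2 up and 1 down of 15, or 5 and 1 over the list alone (adjusted p = 0.00386, and adjusted p = 0.186 with an estimated correlation), and SESN2 was the 1 of 12 repair and metabolism targets that rose, with 2 over the list alone (adjusted p = 3.64e-08, and adjusted p = 0.0719 with an estimated correlation). Cholesterol genes rose in 2 of 27 cases, or 8 over the list alone (adjusted p = 9.17e-14, and adjusted p = 0.00868 with an estimated correlation). Wnt targets fell in 1 of 15 cases, the same over the list alone (adjusted p = 0.00543, and adjusted p = 0.39 with an estimated correlation), with adjusted p = 0.0863 without replicate 1 of the combination. Replication histones passed in 0 of 34 cases, with 0 over the list alone and adjusted p = 0.132. The S phase, heat shock, hypoxia, ribosomal protein, ribosome biogenesis and mitochondrial lists passed with the preset correlation, and each lost its call with a library left out. For mitochondrially encoded genes the median was 0.13 without 5-Ph-IAA replicate 1, which left 1 library in that group. With 1 library left out the count was 16 and 20 (5-Ph-IAA replicates 1 and 2) or 16 and 28 (replicates 1 and 2 of the combination). Each of these 4 fits lost ADM2 (2.83 to 3.29), BBC3 (1.06 to 1.12), PMAIP1 (0.62 to 0.80), BTG2 (1.05 to 1.18), PLK3 (0.96 to 1.02), JUN (0.75 to 0.78), AXIN2 (-1.73 to -1.28), CDC25A (-0.68 to -0.63), MSX1 (-0.86 to -0.80) and TNFRSF10D (-0.82 to -0.72). GADD45A was lost without 5-Ph-IAA replicate 1 (0.84) and combination replicates 1 and 2 (0.92 and 1.03), and LURAP1L without both 5-Ph-IAA replicates (2.13 and 2.47) and combination replicate 1 (2.19).

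The genes that Nutlin raised with and without 5-Ph-IAA overlapped far beyond chance. Of 68 genes raised without it and 59 raised with it, 52 were shared, where 0.233 would be shared by chance (one-sided Fisher exact p = 2.1e-129 across genes, which are not independent replicates). Of 12 and 8 lowered genes, 4 were shared, AXIN2 and CDC25A among them (expected 0.00556, one-sided Fisher exact p = 9.38e-12). Stress-response genes had smaller responses with 5-Ph-IAA in 23 of 27 cases and p53 targets in 56 of 88, but other ways of assigning the libraries gave differences as large.

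Whether 5-Ph-IAA altered the response to Nutlin was tested gene by gene as an interaction. By edgeR 0 genes passed, with 623 at an unadjusted p under 0.05, and DESeq2 called 1. CDKN1A had an interaction of -0.29 ± 0.12 (adjusted p = 0.989), MDM2 0.03 and HNRNPU 0.14. Averaged over both arms, 249 genes answered to Nutlin, 165 up and 84 down, and MDM2 then rose by 0.56 ± 0.073 (adjusted p = 0.00439), a call lost without combination replicate 1 (0.54). Across the 165 raised genes the slope of the response with 5-Ph-IAA on that without was 0.851. That slope runs through the origin and weights the largest responses most. Among these were IL21R, with 7.157 without and 2.535 with 5-Ph-IAA, and ENSG00000286231, with 6.632 and 7.561. Noise in the response without 5-Ph-IAA also pulls the slope down, and its Nutlin pair had a biological coefficient of variation of 0.213. That of the combination pair was 0.0547. The ratio of the summed responses was 0.903. A smaller response with 5-Ph-IAA was seen for 111 genes (67.3%), and the median difference over the 165 was -0.061. An exact two-sided permutation test of that median over the 36 assignments of libraries gave p = 0.167, where 0.0556 is the smallest p it can give. For the 88 p53 targets the median difference was -0.064 (exact permutation p = 0.111) and for the 27 stress genes -0.13 (exact permutation p = 0.222). The slope ranged from 0.577, without vehicle replicate 1, to 1.01, without 5-Ph-IAA replicate 1, as single libraries were left out. The averaged count was 99 and 101 without vehicle replicates 1 and 2, 1662 (658 up, 1004 down) and 1977 (812 up, 1165 down) without Nutlin replicates 1 and 2, 98 and 95 without 5-Ph-IAA replicates, and 84 and 99 without combination replicates. The interaction count was 1035 without Nutlin replicate 1 and 5 without Nutlin replicate 2.

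**Figure D2:**
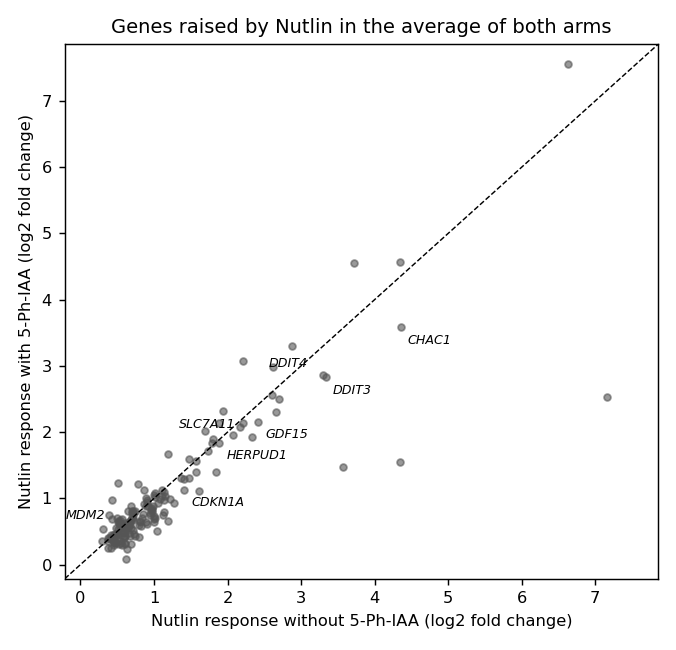
Log2 fold change to Nutlin without 5-Ph-IAA (horizontal) and with it (vertical) for the 165 genes raised by Nutlin over both arms, each point 1 gene from n = 2 libraries per group, with no error bars, and a dashed line of equality. The slope through the origin, which weights the largest responses most, was 0.851, and the ratio of the summed responses was 0.903, with 111 genes below the line.

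As lists, several groups had interaction values that passed only with the preset correlation. Histones had a median interaction of -0.31 (camera adjusted p = 2.09e-16, and adjusted p = 0.366 with an estimated correlation), ribosomal protein genes -0.22 (adjusted p = 2.09e-16, and adjusted p = 0.437 with an estimated correlation) and mitochondrially encoded genes 0.51 (adjusted p = 6.75e-11, and adjusted p = 0.366 with an estimated correlation). Without Nutlin replicate 1 and 2, respectively, the medians were -0.46 and -0.16 for histones, -0.34 and -0.087 for ribosomal protein genes and 0.71 and 0.42 for mitochondrially encoded genes, and these lists passed in each case with the preset correlation. The stress list had -0.13 (adjusted p = 0.000341, adjusted p = 0.361 with an estimated correlation, and adjusted p = 0.134 without Nutlin replicate 1), and hypoxia and glycolysis genes -0.15 (adjusted p = 0.000542, and adjusted p = 0.366 with an estimated correlation). The hnRNP family had 0.15 (adjusted p = 0.0138, and adjusted p = 0.361 with an estimated correlation), with adjusted p = 0.07 and 0.0652 without replicate 1 of vehicle and of 5-Ph-IAA and 0.0925 without replicate 2 of 5-Ph-IAA with Nutlin. The p53 list had an adjusted p of 0.0857.

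Comparing 5-Ph-IAA with vehicle among Nutlin-treated cells, edgeR called 0 genes, with 1404 at an unadjusted p under 0.05, and DESeq2 called 24. CDKN1A had -0.24 (adjusted p = 0.604), MDM2 0.03 (adjusted p = 0.953), which was -0.004 after GC correction, and HNRNPU 0.15 (adjusted p = 0.696). Histones had a median of -0.38 with 0 passing and 27 lowered over the list alone (adjusted p = 3.72e-30, and adjusted p = 0.343 with an estimated correlation), and mitochondrially encoded genes a median of 0.46 with 2 raised over the list alone (adjusted p = 4.11e-10, and adjusted p = 0.343 with an estimated correlation). Without Nutlin replicate 1, edgeR called 2490 genes, 28 lowered histones and 10 raised mitochondrial genes among them, and without replicate 2 it called 42, with a histone median of -0.24 and 0 mitochondrial genes. Ribosomal protein genes had a median of -0.19 (adjusted p = 5.07e-17, and adjusted p = 0.575 with an estimated correlation) and colon epithelial genes -0.15 (adjusted p = 0.00578, and adjusted p = 0.343 with an estimated correlation). The speckle and splicing, hnRNP, nuclear architecture, stress, hypoxia and S phase lists also passed with the preset correlation, had an adjusted p of 0.343 or more with an estimated correlation, and each lost its call with a library left out. Without replicate 2 of 5-Ph-IAA with Nutlin the adjusted p was 0.248 for the speckle list, 0.248 for the hnRNP list, 0.279 for nuclear architecture, 0.351 for stress and 0.31 for hypoxia. It was 0.636 for stress without Nutlin replicate 1, 0.0638 for the hnRNP list, 0.0801 for hypoxia and 0.679 for S phase without Nutlin replicate 2, and 0.222 for S phase without replicate 1 of 5-Ph-IAA with Nutlin.

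At 3 h of 5-Ph-IAA, the time-course set showed a short list of changed genes, most of them raised. CCN1, a secreted matrix protein and YAP target, rose from 10.03 ± 1.12 to 26.5 ± 2.51 CPM, THBS1, the matrix protein thrombospondin 1, from 44.4 ± 1.01 to 90.8 ± 8.31 CPM, and AREG, a ligand of the EGF receptor, from 124 ± 3.12 to 214 ± 0.996 CPM. FOS, an immediate early transcription factor, fell from 33.9 ± 4.9 to 14.6 ± 0.841 CPM. HNRNPU transcript stood at 527 ± 24.8 and 535 ± 16.1 CPM, a value that does not measure the SAF-A protein.

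This comparison asked which transcripts differ 3 h after 5-Ph-IAA. By edgeR 13 of 19049 genes passed, 12 up and 1 down. CCN1 (ENSG00000142871.18, chromosome 1, 85580761 to 85583962, + strand) rose by 1.40 ± 0.18 (adjusted p = 0.0131), C1orf116 by 1.12 ± 0.15 (adjusted p = 0.0134) and THBS1 (ENSG00000137801.11, chromosome 15, 39581079 to 39599466, + strand) by 1.03 ± 0.098 (adjusted p = 0.0017). AMOTL2, an angiomotin and YAP target, rose by 0.93 ± 0.098, DUSP5, a nuclear ERK phosphatase, by 0.84 ± 0.084, AREG (ENSG00000109321.11, chromosome 4, 74445134 to 74455009, + strand) by 0.78 ± 0.073 (adjusted p = 0.0017), EPHA2, an ephrin receptor, by 0.62 ± 0.070 and PLAU, urokinase, by 0.59 ± 0.093 (adjusted p = 0.0494). DKK1, a secreted Wnt inhibitor, rose by 0.50 ± 0.062, and PLK2, a p53-induced kinase, by 0.43 ± 0.062. FOS (ENSG00000170345.11, chromosome 14, 75278774 to 75282230, + strand) fell by 1.21 ± 0.14 (adjusted p = 0.00419). CDKN1A had 0.17 (adjusted p = 0.749), MDM2 0.09 (adjusted p = 0.888) and HNRNPU 0.02 (adjusted p = 0.996).

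**Figure D3:**
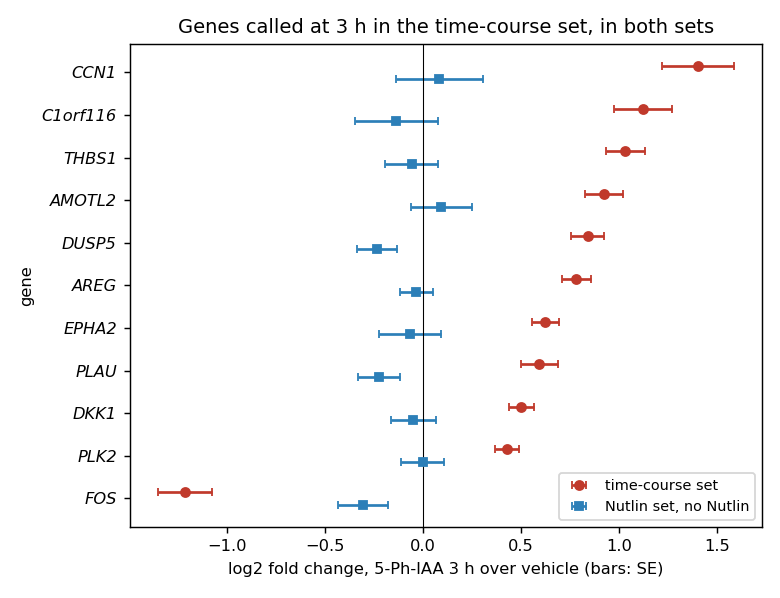
Log2 fold change ± SE (n = 2 per group) of 11 of the 13 genes that passed at 3 h of 5-Ph-IAA over vehicle in the time-course set, with the same genes in the Nutlin set without Nutlin. Over all 13 the medians were 0.782 in the time-course set and -0.057 in the Nutlin set.

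Immediate early genes split 2 up, CCN1 and DUSP5, and 1 down, FOS, of 28, or 9 and 1 over the list alone (camera adjusted p = 7.99e-08, and adjusted p = 0.184 with an estimated correlation). Replication histones passed in 0 of 34 cases, with 3 raised over the list alone (adjusted p = 5.08e-05, and adjusted p = 0.557 with an estimated correlation), and had adjusted p = 0.408 without vehicle replicate 2. The p53 targets rose in 2 of 88 cases, EPHA2 and PLK2, or 6 up and 1 down over the list alone, with a median of -0.048, a mean of -0.011 and an upward test at adjusted p = 0.265. Growth-arrest targets had 1 of 11 raised, or 3 over the list alone (adjusted p = 0.00773, adjusted p = 0.307 with an estimated correlation, and adjusted p = 0.0788 without 3 h replicate 1). The lists of G2 and mitosis, noncoding RNA and snoRNA hosts, stress and cholesterol also passed with the preset correlation, and each lost its call with a library left out. Without 3 h replicate 2 the median was -0.034 for G2 and mitosis, -0.015 for noncoding RNA and -0.071 for cholesterol. The stress list had 0.10 without 3 h replicate 1. PLAU lost its call without 3 h replicate 1 (0.61) and replicate 2 (0.60), and PLK2 (0.44) and C1orf116 (1.08) without replicate 1. The count was 283 and 46 without vehicle replicates 1 and 2 and 23 and 26 without 3 h replicates 1 and 2, and DESeq2 called 52.

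In the Nutlin set, 5-Ph-IAA without Nutlin gave no called change in any of these 13 genes, and 4 of them had the sign seen in the time-course set. THBS1 stood at 68.5 ± 1.45 CPM in vehicle and 65.9 ± 2.69 CPM with 5-Ph-IAA, and AREG at 87.0 ± 1.31 and 85.0 ± 0.885 CPM. FOS stood at 93.4 ± 18.5 and 75.7 ± 2.64 CPM. By edgeR 0 of 17251 genes passed, with 245 at an unadjusted p under 0.05, and DESeq2 called 0. A fit of the compared groups only called 9 genes, 5 up and 4 down, with 508 at an unadjusted p under 0.05. The set shares a spread, with a biological coefficient of variation of 0.114, against 0.071 for the vehicle pair and 0.053 for the 5-Ph-IAA pair. Between Nutlin replicates it was 0.213. The 0 calls thus do not show that 5-Ph-IAA changed nothing. In the fit of the whole set, HNRNPU had 0.01, which was -0.009 after GC correction, CDKN1A 0.05 and MDM2 0.00. Each of the 27 lists had 0 genes passing, also over the list alone. Immediate early genes had a median of -0.12 (adjusted p = 0.00577, and adjusted p = 0.567 with an estimated correlation), with adjusted p = 0.0702 and 0.252 without replicate 1 of vehicle and of 5-Ph-IAA. Stress genes had 0.06 (adjusted p = 0.0166, and adjusted p = 0.512 with an estimated correlation). Their median was 0.0571 and 0.0638 without vehicle replicates 1 and 2 and 0.0234 without 5-Ph-IAA replicate 1, and the call was lost in each case. Inflammatory NF-kB targets had -0.08 (adjusted p = 0.0482, and adjusted p = 0.512 with an estimated correlation), with adjusted p = 0.108 and 0.159 without vehicle replicates 1 and 2 and 0.295 and 0.0634 without 5-Ph-IAA replicates 1 and 2. Hypoxia and glycolysis genes had 0.06 (adjusted p = 0.0482, and adjusted p = 0.617 with an estimated correlation). Their median was 0.0177 without vehicle replicate 2 and 0.0013 without 5-Ph-IAA replicate 1, and the call was lost in each case.

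Whether the 3 h effect differed between the sets was tested directly, and 12 genes passed by edgeR, each with the lower fold change in the Nutlin set. Libraries labelled 3 h were compared, and the time in 5-Ph-IAA is not certain for the Nutlin set. CCN1 differed by -1.33, THBS1 by -1.10, DUSP5 by -1.09 and AREG by -0.83, and immediate early genes as a list by a median of -0.25, with 0 higher and 2 lower, or 1 and 9 over the list alone (camera adjusted p = 3.63e-11, and adjusted p = 0.0359 with an estimated correlation). After GC correction the list with an estimated correlation had an adjusted p of 0.0772. CCN1 lost its call without vehicle replicate 2 (-1.22) and 3 h replicates 1 (-1.42) and 2 (-1.23) of the time-course set, and without vehicle replicate 2 (-1.14) and 5-Ph-IAA replicates 1 (-1.24) and 2 (-1.43) of the Nutlin set. Across 16836 genes, which are not independent replicates, the fold changes in the sets had a Pearson correlation of -0.0076. For 1 treatment effect common to both sets, edgeR called 0 genes, with 872 at an unadjusted p under 0.05, and DESeq2 called 2. That model counts a disagreement between the sets as spread. For the common effect the stress-response list had a median of 0.087 and 22 of 27 members above 0, with 0 passing also over the list alone (camera adjusted p = 0.000259, and adjusted p = 0.131 with an estimated correlation). The ribosomal protein list had a median of 0.027 (adjusted p = 0.0498, and adjusted p = 0.917 with an estimated correlation). Its median was 0.0175 without vehicle replicate 2 and 0.0122 without 3 h replicate 1 of the time-course set. It was 0.0085 without vehicle replicate 2 and 0.0098 without 5-Ph-IAA replicate 1 of the Nutlin set, and the call was lost in each case. The count for the difference was 145 without time-course vehicle replicate 1, 5 without 3 h replicate 2, and 6 without either 5-Ph-IAA library of the Nutlin set.

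Other lists differed between the sets with the preset correlation only. Lower in the Nutlin set were replication histones, by a median of -0.16 with 1 of 34 passing (adjusted p = 5.11e-06, and adjusted p = 0.454 with an estimated correlation), and ribosome biogenesis genes, by -0.09 (adjusted p = 0.000161, and adjusted p = 0.261 with an estimated correlation). Cholesterol genes were higher, by 0.10 (adjusted p = 0.00173, and adjusted p = 0.261 with an estimated correlation). The remaining lists each lost the call with a library left out. S phase genes differed by -0.06 (adjusted p = 0.00724, and adjusted p = 0.34 with an estimated correlation), with adjusted p = 0.0979 without 3 h replicate 1. Inflammatory NF-kB targets differed by -0.14 (adjusted p = 0.00793, and adjusted p = 0.261 with an estimated correlation), with adjusted p = 0.0987 without 5-Ph-IAA replicate 1 of the Nutlin set. Genes of G2 and mitosis differed by 0.05 (adjusted p = 0.0114, and adjusted p = 0.34 with an estimated correlation), with adjusted p = 0.0638 and 0.0547 without 3 h replicates 1 and 2, and 0.0504 and 0.107 without replicate 1 of vehicle and of 5-Ph-IAA in the Nutlin set. Hypoxia and glycolysis genes differed by 0.07 (adjusted p = 0.00724, and adjusted p = 0.449 with an estimated correlation), with adjusted p = 0.125 without time-course vehicle replicate 1, 0.067 without 3 h replicate 2, and 0.129 and 0.107 without vehicle replicate 2 and 5-Ph-IAA replicate 1 of the Nutlin set.

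The list of TGF-beta and mesenchymal genes differed by -0.07 (adjusted p = 0.0238, and adjusted p = 0.261 with an estimated correlation). Its median was -0.451 without time-course vehicle replicate 1 and -0.135 without 3 h replicate 1. It was -0.133 and -0.303 without 5-Ph-IAA replicates 1 and 2 of the Nutlin set, and the call was lost in each case. Noncoding RNA and snoRNA host genes differed by 0.07 (adjusted p = 0.0383, and adjusted p = 0.34 with an estimated correlation). Their adjusted p was 0.271 without time-course vehicle replicate 1, 0.0979 and 0.0698 without 3 h replicates 1 and 2, and 0.121 and 0.0559 without replicate 1 of vehicle and of 5-Ph-IAA in the Nutlin set.

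After 12 h of 5-Ph-IAA many more transcripts differed. SRRM2, a scaffold protein of nuclear speckles, rose from 128 ± 20.8 to 267 ± 29.7 CPM, NEAT1, the noncoding RNA of paraspeckles, from 185 ± 9.31 to 271 ± 1.64 CPM, and MT-ND4, a mitochondrially encoded subunit of complex I, from 53.5 ± 2.77 to 96.9 ± 14.5 CPM. Falling were CCNG1, a p53-induced cyclin, from 246 ± 3.94 to 134 ± 4.61 CPM, LBR, the lamin B receptor of the inner nuclear membrane, from 176 ± 7.18 to 90.9 ± 6.82 CPM, TTK, a spindle checkpoint kinase, from 153 ± 0.654 to 82.2 ± 0.344 CPM, and MSMO1, a cholesterol synthesis enzyme, from 68.5 ± 5.57 to 31.6 ± 3.17 CPM. HNRNPU transcript rose from 527 ± 24.8 to 654 ± 24.9 CPM. Expected counts of HNRNPU, MDM2 and DDIT3 were fractional in 14 of 14 libraries, so reads shared with other genes enter their levels. The same holds for DKK1, PLAU, IER3, TMPO and MALAT1, among others.

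This comparison asked which transcripts differ after 12 h. The labels give the vehicle libraries of this set no time, and the same vehicle served 3 h and 12 h. Time in culture therefore cannot be told apart from time in 5-Ph-IAA. By edgeR 2163 of 19049 genes passed, 645 up and 1518 down, and 223 moved at least 2-fold. SRRM2 (ENSG00000167978.19, chromosome 16, 2752329 to 2772538, + strand) rose by 1.05 ± 0.12 (adjusted p = 0.000443), NEAT1 (ENSG00000245532.13, chromosome 11, 65422774 to 65445540, + strand) by 0.56 ± 0.086 (adjusted p = 0.00187), MT-ND4 (ENSG00000198886.2, mitochondrial genome, 10760 to 12137, + strand) by 0.88 ± 0.11 (adjusted p = 0.000632) and HNRNPU by 0.31 ± 0.063 (adjusted p = 0.00744). CCNG1 (ENSG00000113328.21, chromosome 5, 163437569 to 163446151, + strand) fell by 0.89 ± 0.072 (adjusted p = 0.000171), LBR (ENSG00000143815.15, chromosome 1, 225401502 to 225428925, - strand) by 0.94 ± 0.084, TTK (ENSG00000112742.10, chromosome 6, 80003887 to 80042527, + strand) by 0.90 ± 0.080 and MSMO1 (ENSG00000052802.13, chromosome 4, 165327623 to 165343160, + strand) by 1.08 ± 0.12. MDM2 fell by 0.39 ± 0.066 (adjusted p = 0.00291), and had -0.20 (adjusted p = 0.103) after GC correction. CDKN1A had -0.01 (adjusted p = 0.98), with 0.018 under RLE size factors and 0.011 in DESeq2.

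The fold changes followed the GC content of the transcripts across genes, with a Spearman correlation of 0.337 that fell to 0.01 once a GC trend was taken off each library. The GC trend is a measured feature of the libraries, and its removal, an alternative chosen after seeing the data, left 905 genes, 479 up and 426 down, of which 642 were shared. Replicate pairs also differed along GC, with a correlation of -0.331 for Nutlin, -0.272 for vehicle of the Nutlin set, -0.0932 for vehicle of the time-course set and 0.0487 for the 12 h pair. HNRNPU (0.68, adjusted p = 0.00069), SRRM2 (0.92), NEAT1 (0.67), MT-ND4 (0.99), CCNG1 (-0.54), LBR (-0.57), TTK (-0.66) and MSMO1 (-0.73) passed with the GC trend removed. The 12 h libraries stood apart from the rest and from each other, at -5.31 and -113 on the first principal component and -107 and 26.6 on the second. The count was 961 without 12 h replicate 1, and HNRNPU then lost its call (0.28).

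**Figure D4:**
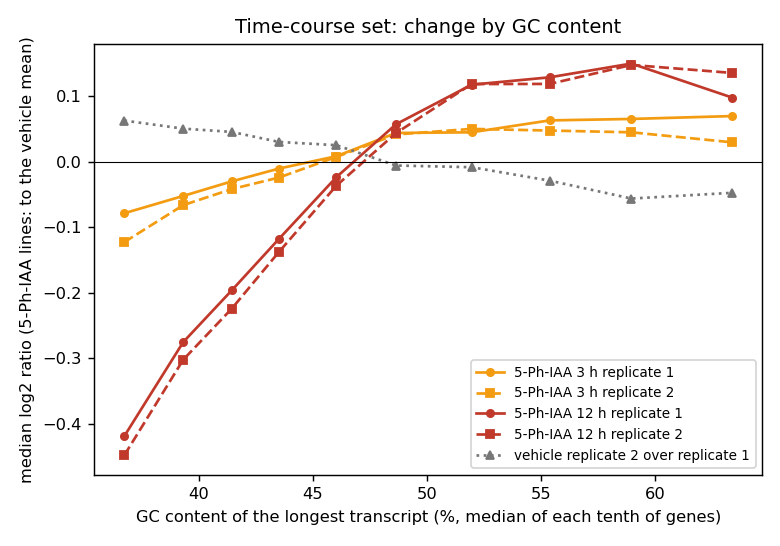
Median log2 ratio to the vehicle mean (vertical) for 10 equal groups of genes ordered by GC content of the longest transcript, in percent (horizontal), in the 5-Ph-IAA libraries of the time-course set, beside vehicle replicate 2 over replicate 1, with no error bars (1 line per library). At 12 h the group lowest in GC, with a median GC of 36.8%, stood at -0.419 and -0.448, and group 9, with 59.0%, at 0.150 and 0.148.

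Nuclear speckle and splicing genes split 6 up and 8 down of 46, or 9 and 10 over the list alone, with a median of -0.014, a mean of 0.0015 and an upward test at adjusted p = 0.847. PRPF8, a core spliceosome protein, rose by 0.70 ± 0.081 with SRRM2, while SRSF3, a splicing factor, had -0.36 and SF3B1, of the U2 particle, had -0.39, and both lost their call after GC correction (-0.06 and -0.16). With GC corrected the list split 10 up and 1 down, or 16 and 3 over the list alone, with a median of 0.093 (adjusted p = 0.00107, and adjusted p = 0.404 with an estimated correlation). The hnRNP family split 3 up and 4 down of 25, or 4 and 5 over the list alone (adjusted p = 0.966), with a median of 0.054 and a mean of -0.010, and HNRNPH1 had -0.54, against -0.10 (adjusted p = 0.392) after GC correction. Nuclear architecture genes split 5 up and 7 down of 36, or 11 and 10 over the list alone (adjusted p = 0.657). Of these SMARCA4, a chromatin remodeler, rose by 0.64, and TMPO, a lamina-associated protein, fell by 0.49 with LBR. Noncoding RNA and snoRNA host genes split 2 up and 4 down of 24, or 3 and 5 over the list alone (adjusted p = 0.847), with TAF1D at -0.59 and -0.16 (adjusted p = 0.212) after GC correction. Mitochondrially encoded genes rose in 4 of 15 cases, or 5 over the list alone, with a median of 0.47 (adjusted p = 1.5e-05, and adjusted p = 0.692 with an estimated correlation). That list had 0.12 (adjusted p = 0.0505) without vehicle replicate 1.

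The p53 targets split 6 up and 15 down of 88, or 7 and 18 over the list alone, with a median of -0.11 (adjusted p = 0.0907, and adjusted p = 0.692 with an estimated correlation). KITLG, the ligand of KIT, fell by 0.75 ± 0.063 and RRM2B, a ribonucleotide reductase subunit, by 0.63 ± 0.086, the latter with -0.21 (adjusted p = 0.15) after GC correction. The repair and metabolism part had 0 up and 4 down of 12, the same over the list alone (adjusted p = 0.0819), the cell-death part 0 and 4 of 15, or 1 and 7 over the list alone (adjusted p = 0.0819), and the growth-arrest part 2 and 1 of 11, the same over the list alone (adjusted p = 0.657). Genes of G2 and mitosis split 6 up and 11 down of 35, or 7 and 14 over the list alone (adjusted p = 0.0819), with MKI67, the proliferation antigen, at 0.67 ± 0.095 and ASPM, a spindle pole protein, at -0.82. S phase genes split 1 up and 4 down of 38, or 3 and 8 over the list alone (adjusted p = 0.536). Replication histones split 1 up and 4 down of 34, or 2 and 4 over the list alone, with a median of -0.089, a mean of 0.006 and adjusted p = 0.244. H4C4 fell by 0.53 and H3C4 by 0.60. Immediate early genes rose in 5 of 28 cases, or 6 over the list alone (adjusted p = 0.03, and adjusted p = 0.692 with an estimated correlation), with ZFP36, an mRNA decay factor, at 1.12 ± 0.21 and CCN1 at 0.77 ± 0.20. The list had adjusted p = 0.0569 without vehicle replicate 2, 0.0611 and 0.0572 without 12 h replicates 1 and 2, and 0.251 after GC correction. ZFP36 lost its call without 12 h replicate 1 (0.99), and CCN1 without vehicle replicate 2 (0.68), without 12 h replicate 1 (0.34) and after GC correction (0.70, adjusted p = 0.0556).

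Many of the largest 12 h changes were in genes that share sequence with others. INO80B-WBP1, a readthrough transcript, stood at 4.08 ± 0.56, GTF2IP4, a pseudogene, at 3.67 and LY6G5B at 2.58, each with fractional expected counts in at least 11 of the 14 libraries. GTF2IP4 (3.55) and LY6G5B (2.48) lost their call without 12 h replicate 1. CTAGE4 and TMEM265 were listed at 0 in both 12 h libraries, against 2.75 ± 0.34 and 2.46 ± 0.0617 CPM in vehicle, with fractional counts elsewhere, so no fold is given. CHSY3, a chondroitin synthase gene with whole counts, fell by 2.93 ± 0.47 (adjusted p = 0.00232), and had -2.23 (adjusted p = 0.0661) without 12 h replicate 1.

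Between 3 h and 12 h of 5-Ph-IAA, NEAT1 and SRRM2 rose and CCNG1 and MDM2 fell. NEAT1 went from 129 ± 14.2 to 271 ± 1.64 CPM and SRRM2 from 114 ± 13.3 to 267 ± 29.7 CPM. DUSP5, DKK1 and PLK2 were lower at 12 h than at 3 h and FOS was higher, but these genes were picked from the same 3 h libraries, so some return is expected without any change. CCNG1 went from 219 ± 1.19 to 134 ± 4.61 CPM, and MDM2 from 314 ± 3.37 to 225 ± 6.53 CPM.

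This comparison asked what separates 12 h from 3 h. By edgeR 1551 genes passed, 448 up and 1103 down, with 788 after GC correction, 423 up and 365 down, 589 of them shared. SRRM2 rose by 1.22 ± 0.12 (adjusted p = 0.000802), NEAT1 by 1.07 ± 0.087 (adjusted p = 0.000309), FOS by 0.94, EGR1, an immediate early transcription factor, by 1.01, HNRNPU by 0.29 ± 0.063 (adjusted p = 0.0151) and MALAT1, a noncoding RNA of speckles, by 0.32. DUSP5 fell by 0.81 ± 0.089, CCNG1 by 0.72 ± 0.072, DKK1 by 0.61, PLK2 by 0.49 ± 0.063 and MDM2 by 0.48 ± 0.066 (adjusted p = 0.00182). CDKN1A had -0.18 (adjusted p = 0.145). The p53 targets split 1 up and 13 down of 88, the same over the list alone (camera adjusted p = 0.00819, and adjusted p = 0.752 with an estimated correlation), and had adjusted p = 0.0583 without 12 h replicate 1, 0.144 among protein-coding genes and 0.285 among whole-count genes. Replication histones fell in 10 of 34 cases, or 15 over the list alone (adjusted p = 7.16e-05, and adjusted p = 0.752 with an estimated correlation), and mitochondrially encoded genes rose in 6 of 15, the same over the list alone (adjusted p = 9.33e-09, and adjusted p = 0.752 with an estimated correlation). The count was 663 and 952 without 3 h replicates 1 and 2 and 612 without 12 h replicate 1. HNRNPU lost its call without 3 h replicate 1 (0.24) and 12 h replicate 1 (0.25), FOS without 12 h replicate 1 (0.88), and MALAT1 without 3 h replicate 1 (0.20) and 12 h replicate 2 (0.26).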

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

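Among the tests below, those with a GC correction or thinned libraries, of a single library, of a response led by p53 targets, of reads shared between genes and of other splits of the 3 h libraries were chosen only after the result was seen.

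The effect of 5-Ph-IAA in libraries labelled 3 h differed between the sets for 12 genes in a direct test of that difference. Of these, 11 are given here. The log2 fold change in the Nutlin set minus that in the time-course set was -1.33 for CCN1, -1.10 for THBS1, -1.09 for DUSP5, -0.83 for AREG, -1.27 for C1orf116, -0.85 for AMOTL2, -0.83 for PLAU, -0.70 for EPHA2, -1.53 for SEMA7A, a membrane-anchored semaphorin, and -0.85 for the histone gene H4C11. Immediate early genes differed by a median of -0.25. SLC2A3P1, a pseudogene, had a fitted difference of -9.18, but was listed at 0 in both vehicle libraries of the time-course set and holds fractional counts, so this number is no measure of size. PLAU (0.0505), AMOTL2 (0.0691), H4C11 (0.0504), C1orf116 (0.0504) and CCN1 (0.0676) missed an adjusted p of 0.05 after GC correction. With RLE size factors AMOTL2, PLAU, CCN1 and C1orf116 lost their call, and with the replicate number as a block these 4, H4C11 and SLC2A3P1 did. THBS1, DUSP5 and AREG passed with each library left out in turn. CCN1 was lost in the time-course set without vehicle replicate 2 (-1.22) and 3 h replicates 1 and 2 (-1.42 and -1.23), and in the Nutlin set without vehicle replicate 2 (-1.14) and 5-Ph-IAA replicates 1 and 2 (-1.24 and -1.43). Without 3 h replicate 2 of the time-course set, the calls of SEMA7A (-1.47), EPHA2 (-0.69), H4C11 (-0.76), AMOTL2 (-0.76), C1orf116 (-1.33), PLAU (-0.83) and SLC2A3P1 (-8.64) were lost. AMOTL2 (-0.79 and -0.90), C1orf116 (-1.18 and -1.36), PLAU (-0.83 for each) and H4C11 (-0.86 and -0.83) were lost without either vehicle library of the Nutlin set. AMOTL2 (-0.97 and -0.74), C1orf116 (-1.32 and -1.23), PLAU (-0.83 for each), H4C11 (-0.83 and -0.87) and EPHA2 (-0.72 and -0.69) were lost without either 5-Ph-IAA library of that set, and SEMA7A without replicate 1 (-1.45). AMOTL2 (-0.92), C1orf116 (-1.21) and PLAU (-0.83) were lost without 3 h replicate 1, and AMOTL2 (-0.82), C1orf116 (-1.18) and SLC2A3P1 (-9.10) without time-course vehicle replicate 2.

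For these 3 h genes, depth was tested by thinning the time-course libraries to 12.65 M counts, where the median size of the 13 called changes was 0.819 against 0.841 before, and 12 of the 13 passed. After GC correction the median size was 0.792, with all 13 passing. These 13 genes were picked in these libraries, and thinning leaves the expected size of a change as it was. The tests show that neither lower depth nor GC correction removed these changes in the time-course set, but do not test the difference between sets. In that difference 7 genes passed after GC correction, against 12 before. The median size of the 13 changes was no lower than 0.821 with any 1 of the 4 libraries left out. Genes that passed in these libraries were bound to keep much of their size, so a part played by a single library stays open. The sets also differ in whatever set their cultures and library preparation apart, which the labels do not describe, and no biological explanation was tested. For the 3 h effect common to both sets 0 genes passed in edgeR, with 872 at an unadjusted p under 0.05 and 2 called by DESeq2. Since the real split gave 0, all 34 splits of the 8 libraries give at least as many by construction. Another split gave up to 2, and this says nothing about chance.

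Genes on the stress list rose more than those on the p53 list with Nutlin, and membership does not show what raised a gene. A single library does not carry this, since the lowest of 4 library medians of the stress list was 0.829, and the list median was 0.876 after GC and length correction against 0.869 before. The stress median lay above the upper quartile of the p53 list by at least 0.345 in each of the 4 libraries, which describes the pattern again and leaves open whether p53 targets lead the response. As a hypothesis, Nutlin may engage the stress response beside p53 in these cells, which needs p53-deficient cells to test. For the Nutlin effect as a whole, the real split of the 8 libraries gave 307 genes in a model without the interaction. The others of the 34 splits that could be fitted gave 1 at most. Those splits leave the Nutlin effect in the spread, which keeps their counts low, so they do not measure chance.

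At 12 h of 5-Ph-IAA, thinning all libraries of the set to the shallowest left 1704 genes, which argues against the depth of that library as the whole cause. Of 2119 called genes with a GC value, 641 kept their sign and passed after GC correction, so a change in GC-dependent expression and a GC bias between libraries cannot be told apart for the rest, because the trend goes with the group in both 12 h libraries. Among the 63 called genes past 8-fold, 36 (57.1%) held fractional counts in most libraries, against 25.9% of other called genes, in line with reads shared between near-identical genes as a source of the most extreme values. A biological hypothesis that remains is that longer 5-Ph-IAA treatment changes transcript levels. A longer time course with an untagged control and vehicle libraries at each time would test it. The vehicle group of this set has no stated time, so time in culture cannot be told apart from 5-Ph-IAA treatment.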

How the results depend on the processing

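Choices of method and the alternatives called planned were fixed before the data were examined, and the alternatives of GC correction, whole-count genes, thinning and the shortened p53 list were chosen after seeing the data. Over all alternatives, 9112 of 10056 values of named genes kept their side of the threshold, 814 lost and 127 gained a call, and 3 reversed. The 9112 include values without a call that changed sign, as for HNRNPU and MDM2 after GC correction in the Nutlin set. Of 1282 list values, 1006 stayed, 274 lost their call and 2 reversed. The causes of the differences below were not tested, except that leaving out a library or a group removes samples.

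DESeq2 called 52 genes at 3 h, 152 for Nutlin, 24 for 5-Ph-IAA in Nutlin cells, 1 for the interaction, 2 for 3 h in both sets and 40 for the difference between sets. RLE factors gave 8 for that difference. Without the low-count filter the counts were 193 at 3 h, 2448 for 12 h over 3 h, 405 for Nutlin, 270 for Nutlin in 5-Ph-IAA cells, 53 for 5-Ph-IAA in the Nutlin set, 136 in Nutlin cells, 57 for the interaction, 635 for Nutlin averaged, 110 for 3 h in both sets and 177 for their difference, and the response slope was 0.681. The replicate block gave 45 at 3 h and 6 for the difference. Compared groups alone gave 1391 at 12 h, 27 for Nutlin, 622 for Nutlin in 5-Ph-IAA cells and 9 for 5-Ph-IAA in the Nutlin set. Protein-coding genes alone gave 29 at 3 h, and whole-count genes 34 at 3 h and 1 in both sets. GC correction gave 905 at 12 h, 788 for 12 h over 3 h, 134 for Nutlin, 1 for 3 h in both sets and 7 for the difference.

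With each library left out in turn, the lone library being assumed to vary like the others, counts ranged from 23 to 283 at 3 h, 961 to 2446 at 12 h, 612 to 1545 for 12 h over 3 h, 25 to 2131 for Nutlin, 16 to 28 for Nutlin in 5-Ph-IAA cells, 0 to 2490 for 5-Ph-IAA in Nutlin cells, 0 to 1035 for the interaction, 84 to 1977 for Nutlin averaged, 0 to 2 for 3 h in both sets and 5 to 145 for the difference. The response slope ranged from 0.577 to 1.01.

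Of the named genes with a call, 3 reversed with GC corrected, namely CHORDC1 (0.071) and IFIT5 (0.005) at 12 h over vehicle and RPS3A (0.008) at 12 h over 3 h. Sign changes of genes without a call are not among these 3. Among whole-count genes the noncoding RNA and snoRNA host list reversed at 3 h (0.198) and in the difference between sets (-0.251). The p53 list with Nutlin kept its call under every alternative run. Depth limits the 12 h comparison, where replicate 2 held 3.54 M counts and thinning all libraries to that total left 1704 genes.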

Other observations

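The tests with a GC correction and the comparison of replicate differences with the difference between sets were chosen only after the results were seen.

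After 12 h of 5-Ph-IAA, genes of cholesterol and fatty acid synthesis and of protein folding were also among those called. Cholesterol genes split 3 up and 7 down of 27, or 3 and 8 over the list alone (camera adjusted p = 0.0907, and adjusted p = 0.00732 after GC correction, with adjusted p = 0.404 with an estimated correlation there). FASN, fatty acid synthase, rose by 0.54 and IDI1, an isoprenoid enzyme, fell by 0.63 with MSMO1. Hypoxia and glycolysis genes fell in 4 of 27 cases, or 1 up and 7 down over the list alone (adjusted p = 0.347), among them BNIP3, a mitophagy receptor, at -0.47, a call lost without vehicle replicate 1 (-0.33) and without 12 h replicates 1 (-0.61) and 2 (-0.40). Heat shock genes split 4 up and 3 down of 18, or 6 and 5 over the list alone (adjusted p = 0.536), with AHSA1, an HSP90 cochaperone, at 0.31, lost without 12 h replicate 1 (0.30) and after GC correction (0.22). Stress-response genes split 2 and 2 of 28, or 2 and 4 over the list alone, with a median of 0.098, a mean of -0.17 and an upward test at adjusted p = 0.347. Ribosome biogenesis genes split 4 and 2 of 30, or 6 and 4 over the list alone (adjusted p = 0.164), with NCL, nucleolin, at 0.52 ± 0.063 (adjusted p = 0.000555), and ribosomal protein genes 4 and 5 of 74, the same over the list alone (adjusted p = 0.657). Wnt targets rose in 2 of 16 cases, the same over the list alone (adjusted p = 0.0831), and colon epithelial genes in 2 of 13, or 3 over the list alone (adjusted p = 0.209), with KRT18, a keratin, at 0.34, lost without 12 h replicate 1 (0.29) and after GC correction (0.21). AHR and xenobiotic genes had 1 up of 12 (adjusted p = 0.657), the amino acid transporter SLC7A5 at 0.56. EMT genes had 1 down of 19, SKIL, a repressor of SMAD signaling, at -0.63, with a median of 0.33 and an upward test at adjusted p = 0.347, and SKIL was lost without vehicle replicate 2 (-0.56), without 12 h replicate 1 (-0.79) and after GC correction (-0.076). Interferon genes had 1 down of 25, with 0 over the list alone (adjusted p = 0.847), namely IFIT5 at -0.38, which was 0.005 after GC correction and lost its call without vehicle replicate 1 (-0.27) and 12 h replicates 1 (-0.41) and 2 (-0.35). NF-kB genes had 0 of 20 passing and 0 over the list alone (adjusted p = 0.536), markers of other cell types 0 of 8 (adjusted p = 0.847), and long neuronal genes 1 down of 11 (adjusted p = 0.906).

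With Nutlin alone, VEGFA was the 1 of 28 hypoxia and glycolysis genes that rose (adjusted p = 0.207), and IER3, an early response gene, at 0.51, the 1 of 17 NF-kB genes (adjusted p = 0.597), with a list median of -0.057 and a mean of 0.089. IER3 was lost without vehicle replicates 1 (0.47) and 2 (0.55) and after GC correction (adjusted p = 0.067). By edgeR 0 genes passed in the remaining lists. Camera gave them, each time with the value for an estimated correlation, adjusted p = 0.00308 and 0.494 for G2 and mitosis, 0.0048 and 0.147 for speckles, 0.00721 and 0.123 for hnRNPs, 0.017 and 0.191 for nuclear architecture, 0.00378 and 0.195 for ribosome biogenesis, 0.0323 and 0.165 for AHR, and 0.0144 and 0.147 for colon epithelium. The first of these values was 0.563 for G2 and mitosis without Nutlin replicate 1, 0.0816 for nuclear architecture and for ribosome biogenesis without vehicle replicate 1, and 0.0603 for colon epithelium without Nutlin replicate 2. For AHR it was 0.217 without vehicle replicate 1 and 0.0663 and 0.0724 without Nutlin replicates 1 and 2. Heat shock had adjusted p = 0.19, interferon 0.627, EMT 0.484, other cell types 0.645, long neuronal genes 0.926 and S phase 0.176.

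The difference between the Nutlin replicates resembled, across 10119 genes, the difference between the vehicle groups of the sets, with a correlation of 0.435, or 0.371 after a GC trend was taken off, against -0.106 for the 5-Ph-IAA replicates and -0.182 for the combination.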
